A study of Mus musculus with 8 samples.

How the data were processed

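Total RNA of neural stem and progenitor cells from mouse embryos at stage E14.5, on a mixed C57BL/6 and 129S1 background, was labelled with biotin and hybridized to Illumina MouseRef-8 V2 bead arrays, per the labels' protocols. The labels name 4 samples of each of 2 genotypes, control (floxed Prmt5 without Cre) and Prmt5-depleted (floxed Prmt5 with Nestin-Cre), with replicate numbers 1 to 4. Every array column was matched to its sample by its name, and 0 columns were left without a sample.

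The authors deposited a table of intensity values, not normalized, per the file headers, with 1 signal for each of 25662 probes on each array. The same deposited table gives a detection p-value per probe and array, per the file headers, and its values move in steps of about 0.00125. The scanner software and any earlier background step are not given in the sources used here. The lowest deposited intensity of an array was between 44.6 and 51.4 and the highest between 45318 and 51344. The authors' series matrix holds a second set of intensity values, whose processing is not stated. Set against the first table, each of its columns had a Spearman correlation of 1 with its own array, and quantile normalization of the first table gave the same values within 2.18e-11. It is therefore on a linear scale, quantile normalized, without centring or background subtraction. As the arrays have 1 colour, no ratio direction arises. The column medians of the matrix were 95.8, 95.7, 95.7 and 95.8 for control 1 to 4 and 95.8, 95.7, 95.7 and 95.7 for Prmt5-depleted 1 to 4. These values served as an alternative only.

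The non-normalized signals were corrected for background by normexp with parameters inferred from the detection p-values, an offset of 16 was added, and arrays were quantile normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3, statmod 1.5.0). An offset limits the noise of dim probes and pulls their fold changes towards 0, and quantile normalization takes the distribution of signal to be alike on all arrays, so a change shared by most genes would not be seen. Mean signals were 449, 543, 544 and 598 on control 1 to 4, and 558, 573, 512 and 472 on Prmt5-depleted 1 to 4. A probe was kept when its detection p-value was under 0.05 on at least 4 of the 8 arrays. This kept 13196 probes, 51.4% of the total, and left out 12466.

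Probes were named from the platform annotation, in which 23943 probes have 1 gene, 0 have several and 1719 have none. Symbols were updated through Entrez IDs in a RefSeq gene table of assembly GRCm38.p6, used for names only. Of the probes, 23927 matched and 0 symbols changed. Among the kept probes 774 had no gene name. No genome build is named by the sources used here, so no coordinates are given. A gene was represented by its kept probe with the highest mean signal over all arrays, which gave 9001 genes.

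Genotypes were compared per probe and per gene with a linear model and moderated variances (lmFit and eBayes in limma) without covariates, two-sided, with Benjamini-Hochberg adjustment at 0.05. All p-values named adjusted come from this adjustment over all genes tested unless a list alone is named. Where a gene had a detection p-value of 0.05 or more on all 4 arrays of a genotype, the fold is a lower bound. It sets the mean of the bright genotype against the mean over the dim arrays of the higher of the gene's own value and the lowest value of a detected probe on that array, called the floor. Where 1 or 2 of the 4 arrays detected a named gene, its fold is given as estimated and also with values under the floor raised to it.

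Gene lists for 19 pathways, complexes and cell types were fixed before the data were examined. They cover p53 target genes, the PRMT family, Sm, U snRNP and LSm proteins, the methylosome and snRNP assembly, SR proteins and hnRNPs, mitosis and G2/M, DNA replication and S phase, DNA damage signalling and repair, apoptosis, the integrated stress and unfolded protein responses and the interferon response. The cell types are neural stem cells and radial glia, neurons, astrocytes, oligodendrocyte lineage, microglia and macrophages, endothelium, mesenchymal, pericyte and meningeal cells, and erythroid cells. No measured gene is on more than 1 of the 19 lists. Each list was tested against the other genes with camera at a preset correlation of 0.01 and, as an alternative, with an estimated correlation, with adjustment over the 19 lists. Fry, also run, asks whether the genes of a list move one way on balance and does not compare them with other genes. A further 8 lists were chosen after the data were seen.

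The genes named were set by a rule fixed before the data were examined. It takes Prmt5, Mdm4, Mdm2 and Trp53 at all probes, the 10 largest rises and the 10 largest falls among genes past the threshold whose genotypes do not overlap, for each list up to 4 called members with the smallest adjusted p (2 where none was called), and up to 2 called members that go against their list. Any other gene is said to have been chosen after its values were seen where it is first named, or completes a count of 5 or fewer.

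The steps were tested on simulated data in which 200 of the 9001 genes of the genotype comparison were changed. A log2 change of 2 was recovered in 66 of 66 genes, one of 1 in 65 of 67 and one of 0.5 in 13 of 67, and 8 unchanged genes were called (5.3% of the calls). Of 5 lists shifted by 0.5 log2 units all 5 were found, and 0 of 14 others were called. The simulated genes varied independently of each other. The list result therefore does not cover lists whose genes vary together, such as mitosis (estimated correlation 0.422) and replication (0.443). Far fewer genes were changed than the 48.6% called in the data, so the rates may not carry over. Of 200 genes given probes with opposite changes, 192 were found among 2432 genes with several kept probes.

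Alternatives fixed before the data were examined were no background correction, cyclic loess or median scaling in place of quantile normalization, the authors' matrix, no filter, a detection p-value under 0.01 on all 8 arrays, the replicate number as a block, array weights, an intensity trend with a robust prior, the mean over a gene's probes, a test against a 1.2-fold change, and leaving out each array. Added after the data were seen were a covariate for the split of the arrays within the genotypes, each side of that split alone, and the arrays without those carrying Xist signal. The test of lists over other splits of the arrays was repeated without the detection filter, also chosen after the data were seen.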

Results

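Gene expression was measured in neural stem and progenitor cells of mouse embryos at stage E14.5. Prmt5, an enzyme that places symmetric dimethyl marks on arginines of histones, Sm proteins and other targets, was either intact or deleted. The control cells carried a floxed Prmt5 gene without Cre recombinase. The Prmt5-depleted cells carried the same gene with Cre driven by Nestin, a gene active in neural progenitors. Effects of Cre itself and of Prmt5 loss therefore cannot be told apart here. Each genotype was hybridized to 4 bead arrays, so 8 arrays were compared. Before normalization the mean signal of an array lay between 449 and 598 intensity units, and between 12518 and 13602 of the 25662 probes were detected. The number of arrays limits the precision of each value. The labels do not say whether the arrays of a genotype hold RNA of separate embryos or cultures, so p-values measure the spread between these samples.

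The 8 arrays separated by genotype along the first principal component, which held 74.1% of the variance. Pearson correlations of normalized log2 signals were 0.979 to 0.993 within a genotype and 0.912 to 0.933 between genotypes. The second component held 10.5% of the variance and did not follow genotype. Control 4 and Prmt5-depleted 1 and 3 lay apart from the other 5 arrays along it.

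**Figure D1:**
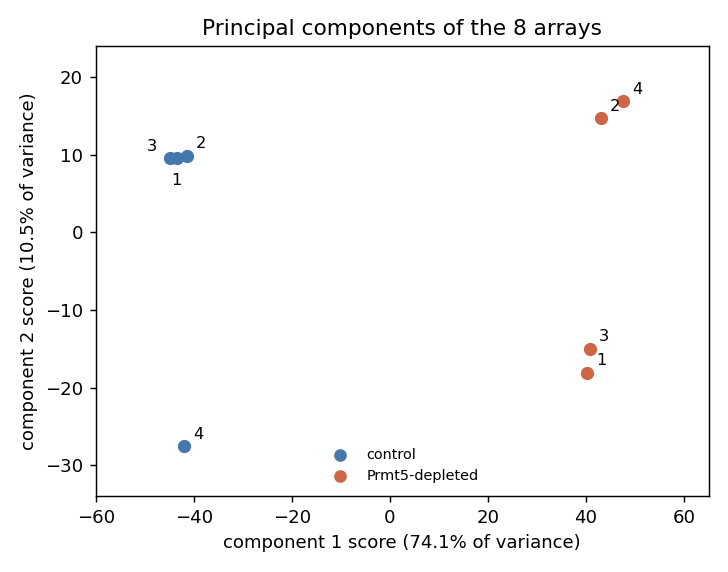
Scores of the 8 arrays on the first and second principal components of normalized log2 signals, in score units, with replicate numbers beside the points (blue, control; orange, Prmt5-depleted). The genotypes lie on opposite sides of component 1 (74.1% of variance), and control 4 and Prmt5-depleted 1 and 3 lie at the low end of component 2 (10.5%).

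The first question was whether Prmt5 transcripts were lower in the cells labelled as depleted. Prmt5 fell from 10.39 ± 0.25 (SD, n = 4) to 7.69 ± 0.41 (SD, n = 4) on the log2 scale at its brightest probe, ILMN_2983093, a 6.49-fold fall (log2 standard error 0.20, adjusted p = 1.11e-06). The other probes of the gene, ILMN_2720634 and ILMN_2722455, fell 8.45-fold and 6.06-fold. All 3 probes remained detected on all 4 Prmt5-depleted arrays. At each of them every Prmt5-depleted array lay below every control array. Where these probes lie relative to the deleted part of the gene was not determined here, so the fall matches the labels in direction and does not measure the deletion itself.

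Loss of Prmt5 went with a broad change of the transcriptome, with Ass1 and Vgf among the largest rises and Pdgfra and Gpr17 among the largest falls. Of 9001 genes tested, 2164 were higher and 2207 lower in Prmt5-depleted cells, which is 48.6% of the genes. At probe level, 2913 probes were higher and 3256 lower among 13196 tested. A change of at least 1.5-fold was estimated for 1534 of the higher and 1359 of the lower genes, and one of at least 2-fold for 812 and 527. The 4 arrays of each genotype did not overlap in 4031 genes, 44.8% of those tested, where chance gives 2.86%. The median log2 fold change over all genes was -0.04.

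The 10 largest rises with no overlap between genotypes were led by Ass1, the argininosuccinate synthase of the urea cycle, with an estimate of 31.1-fold (adjusted p = 8.98e-09). In control cells Ass1 was detected on only 1 of 4 arrays, and with control values raised to the detection floor the rise was 24.6-fold. Vgf, a precursor of secreted neuropeptides, rose at least 16.9-fold, as none of the 4 control arrays detected it. The granins Chgb and Scg2, proteins of dense-core secretory granules, rose 14.7-fold and 14.3-fold, the latter from a signal that 1 of 4 control arrays detected (11.5-fold from the floor). Pde1a, a calmodulin-dependent phosphodiesterase, rose 17.7-fold, and the mitochondrial creatine kinase Ckmt1 rose 14.9-fold. The others were Wfdc2 at 17.6-fold (detected on 2 of 4 control arrays; 14.9-fold from the floor), the matrix protein gene Thbs2 at 14.9-fold, the copine Cpne4 at 13.6-fold and the galectin Lgals3 at no less than 10.4-fold, the last again not detected on any control array. Their adjusted p-values lay between 8.98e-09 and 3.46e-06.

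The 10 largest falls included Pdgfra and Gpr17, both on the list of oligodendrocyte lineage markers. Pdgfra, the growth factor receptor of oligodendrocyte precursors, fell from 10.08 ± 0.31 to 4.74 ± 0.22 (SD, n = 4 each), and Gpr17, a receptor of committed precursors, from 9.07 ± 0.48 to 4.61 ± 0.07 (SD, n = 4 each). Neither was detected on any Prmt5-depleted array, so Pdgfra was at least 30.6-fold and Gpr17 at least 15.2-fold lower (adjusted p = 8.98e-09 and 5.44e-08). Mfng, a glycosyltransferase that modifies Notch receptors, fell 12.7-fold, and Hes5, a transcriptional target of Notch in neural stem cells, fell 8.79-fold. Bcas1, a gene of differentiating oligodendrocytes, fell 9.28-fold, and Bcan, which encodes the proteoglycan brevican, fell 8.08-fold. The remaining falls were Mgarp (14.8-fold, detected on 1 of 4 Prmt5-depleted arrays; 13.1-fold to the floor), Moxd1 (12.9-fold), Cmtm5 (9.18-fold) and Rgcc (8.86-fold).

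**Figure D2:**
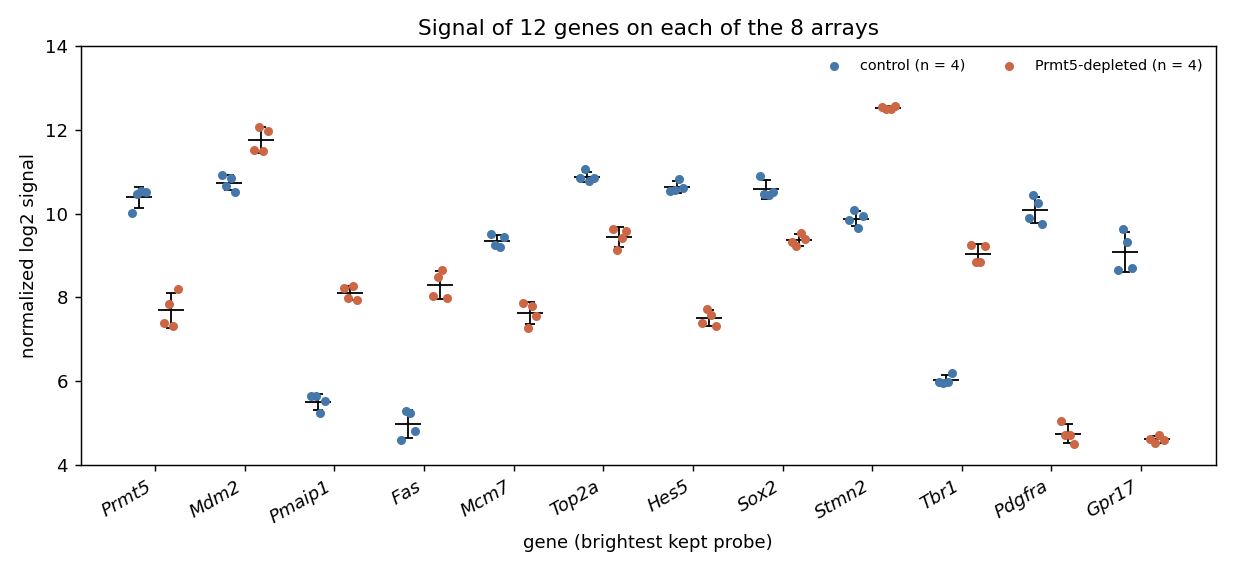
Normalized log2 signal of 12 genes on each array (points; blue, control; orange, Prmt5-depleted), with the mean and SD of the 4 arrays of each genotype in black. Prmt5 lies near 10.39 in control and 7.69 in Prmt5-depleted cells, Mdm2, Pmaip1, Fas, Stmn2 and Tbr1 lie higher in Prmt5-depleted cells, and Mcm7, Top2a, Hes5, Sox2, Pdgfra and Gpr17 lie lower.

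The title of the study names Mdm4, an inhibitor of p53, as a transcript that senses splicing defects, and the next comparison concerned Mdm4, Mdm2 and p53 target genes. Genes activated by p53 rose together. Of 27 measured, 19 rose, 1 fell and 7 did not pass the test, and adjusted over the list alone 20 rose and 1 fell. Without the detection filter 30 were measured, 19 rose and 0 fell, and the median log2 change was 0.818 in place of 0.919. Pmaip1, which encodes the pro-apoptotic protein Noxa, rose 6.05-fold (log2 change 2.60, standard error 0.13, adjusted p = 1.02e-07), and the death receptor gene Fas rose 9.94-fold from a signal that 1 of 4 control arrays detected (8.04-fold from the floor). Dcxr rose 7.64-fold, and Trp53inp1, a stress-induced p53 cofactor, rose 3.86-fold. Chosen after their values were seen, other members were the cell cycle inhibitor Cdkn1a, which rose 4.22-fold (adjusted p = 2.46e-06), and Ccng1, which rose 3.89-fold. Ddit4, an inhibitor of mTOR signalling, fell 2.06-fold (adjusted p = 0.02). Its call was lost without control 2 (adjusted p = 0.0604) or control 3 (adjusted p = 0.0524). The list stood above the other genes in camera (adjusted p = 5.46e-08), and also with an estimated correlation (adjusted p = 0.0335). That second call was lost once the fit held a covariate for the split of the arrays along component 2 (adjusted p = 0.0849 with an estimated correlation). This covariate was chosen after the data were seen, and at the preset correlation the list stayed called with it. The median log2 change was 0.87 with it and 0.92 without, and 19 genes rose and 1 fell in both.

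Mdm2, the ubiquitin ligase of p53 and itself a p53 target, rose from 10.74 ± 0.18 to 11.76 ± 0.30 (SD, n = 4 each) at ILMN_1250774, which is 2.03-fold (adjusted p = 0.000281). A second bright probe, ILMN_2850753, rose 2.18-fold. The third, ILMN_1229882, was dim, with a log2 difference of 0.15 and an adjusted p of 0.403. Total Mdm4 signal was near background in both genotypes. Its 3 probes were detected on at most 1 of 4 arrays per genotype and were not kept for testing. In a fit of all probes their log2 differences were -0.09, -0.07 and -0.06, with adjusted p between 0.715 and 0.837. These probes could not show a change of Mdm4 level at this signal, and a change of its splicing was not measured here. For Trp53, which encodes p53, no probe carried the gene name in the annotation used here.

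Most measured genes of cell division fell. Of the genes of mitosis and G2/M, 26 of 40 passed the detection filter and all 26 fell, with the same count adjusted over the list alone, and their log2 changes ran from -1.78 to -0.63. The topoisomerase Top2a fell 2.71-fold, the spindle motor Kif11 2.83-fold, the centromeric histone Cenpa 2.39-fold and the cytokinesis motor Kif23 2.52-fold, with adjusted p between 5.94e-06 and 2.94e-05. Of 36 measured genes of DNA replication and S phase, 33 fell, none rose and 3 did not pass the test, and adjusted over the list alone 35 fell. Without the filter 26 of 34 genes of mitosis and 32 of 40 of replication fell, and 0 rose in either list. The polymerase subunit gene Pold1 fell 3.86-fold, the helicase genes Mcm7 and Mcm2 fell 3.28-fold and 2.70-fold, and the clamp loader Rfc4 fell 2.71-fold. Camera gave adjusted p = 2.12e-10 for mitosis and 3.8e-11 for replication. Neither call held with an estimated correlation (adjusted p = 0.191 for both lists). Camera p-values as small as those of the real genotypes also arose in 2 of the 35 splits of the arrays for mitosis and 6 for replication, the real split included. The others kept 3 arrays of a genotype together and so carried part of the genotype difference. Without the filter only the real split gave a value as small for either list.

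Of 25 measured genes of DNA damage signalling and repair, 17 fell, 1 rose and 7 did not pass the test, with the same counts adjusted over the list alone. The helicase Blm fell 2.91-fold, Mre11a 2.26-fold, Rad18 2.37-fold and Brca2 2.17-fold. Trp53bp1, which binds at double-strand breaks, rose 1.82-fold (adjusted p = 0.00027). Camera gave adjusted p = 0.000213 for the list, a call that was lost with an estimated correlation (adjusted p = 0.0755). Among 19 measured genes of the apoptosis machinery, 9 rose, 2 fell and 8 did not pass the test, with the same counts adjusted over the list alone. The inflammatory caspase Casp1 rose at least 2.00-fold, Bid rose 2.27-fold and Hrk rose 2.23-fold. Bcl2l1, whose main product inhibits apoptosis, rose 2.57-fold, while the death receptor adaptor Fadd fell 1.66-fold and Casp2 fell 1.43-fold. The apoptosis list as a whole was not called (camera adjusted p = 0.0934). Without the detection filter 23 of its genes were measured, 8 rose and 2 fell, and the median log2 change was -0.002 in place of 0.206.

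Markers of neurons rose. Of 26 measured, 23 rose, 1 fell and 2 did not pass the test, and adjusted over the list alone 23 rose and 2 fell. Without the detection filter 35 were measured, 23 rose and 1 fell, and the median log2 change was 1.302 in place of 1.588. Tbr1, a transcription factor of early cortical neurons, rose 8.10-fold (log2 change 3.02, standard error 0.13, adjusted p = 5.44e-08). Stmn2 rose 6.25-fold, the growth cone protein gene Gap43 4.34-fold and the synaptic vesicle gene Syp 4.10-fold. Neurog2, a proneural factor of progenitors that commit to neurons, fell 2.62-fold (adjusted p = 0.0036). Camera called the list (adjusted p = 1.66e-10), also with an estimated correlation (adjusted p = 0.0375), but not when the component 2 split was added to that test (adjusted p = 0.0849 with an estimated correlation). At the preset correlation the list stayed called with the split as a covariate. The median log2 change was 1.61 with the split and 1.59 without, and 23 genes rose in both.

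Oligodendrocyte lineage markers moved the other way. Of 10 measured, 9 fell and 1 rose, with the same counts adjusted over the list alone. Beside Pdgfra and Gpr17, the myelin lipid enzyme Ugt8a fell 3.17-fold (adjusted p = 4.14e-06). Mbp, which encodes myelin basic protein and also has other transcripts expressed outside myelin, rose 4.16-fold (adjusted p = 2.29e-05). Camera called the list (adjusted p = 0.000213), also with an estimated correlation (adjusted p = 0.0375). The second call was lost when that test included the component 2 split (adjusted p = 0.0849 with an estimated correlation). At the preset correlation the list stayed called with the split as a covariate. The median log2 change with the split was -1.22 in place of -1.27, and 9 genes fell in both. With only control 4 and Prmt5-depleted 1 and 3, where the lone control array is assumed to vary like the others, camera gave adjusted p = 0.0546.

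Markers of neural stem cells and radial glia did not move as 1 group. Of 21 measured, 9 fell, 4 rose and 8 did not pass the test, and adjusted over the list alone 10 fell and 4 rose. Beside Hes5, the stem cell factor Sox2 fell 2.32-fold and the Notch target Hes1 fell 2.63-fold. Id4, an inhibitor of basic helix-loop-helix factors, rose 2.79-fold and the cortical patterning gene Lhx2 rose 1.72-fold. Camera did not call the list (adjusted p = 0.0875). Of 9 measured astrocyte markers, 4 rose, 1 fell and 4 did not pass the test, and adjusted over the list alone 5 rose and 2 fell. Clu, which encodes clusterin, rose 10.1-fold, Sparcl1 3.09-fold and the glutamate transporter Slc1a2 2.17-fold, while Ntsr2 fell 4.06-fold. The astrocyte list was not called (camera adjusted p = 0.11). Without the detection filter 13 of its genes were measured, 4 rose and 2 fell, and the median log2 change was 0.095 in place of 0.359.

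**Figure D3:**
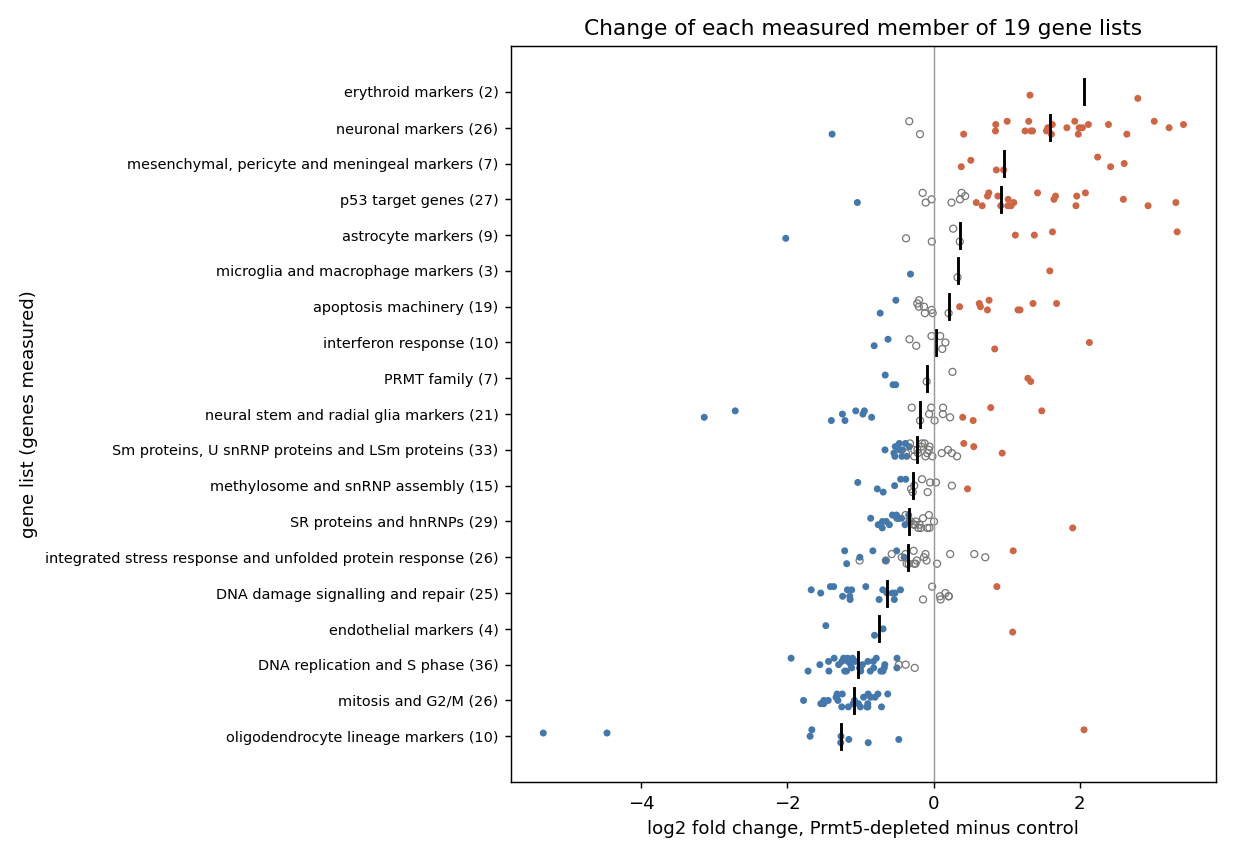
Log2 fold change, Prmt5-depleted minus control, of each measured member of 19 gene lists (points; orange, rose; blue, fell; open, not past the test), with the list median as a black bar and the number of measured genes in parentheses. All 26 mitosis genes lie below 0, 23 of 26 neuronal markers rose, and 9 of 10 oligodendrocyte lineage markers fell.

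Because Prmt5 methylates Sm proteins during assembly of spliceosomal snRNPs, genes of the splicing machinery were examined as groups. List medians were between -0.34 and -0.10, with larger changes in single genes. Of 29 measured SR proteins and hnRNPs, 15 fell, 1 rose and 13 did not pass the test. Srsf9 fell 1.69-fold, Hnrnpf 1.81-fold and Hnrnpk 1.62-fold, and Srsf12 rose at least 3.27-fold, as no control array detected it. Camera called the list (adjusted p = 0.00416), but not with an estimated correlation (adjusted p = 0.199). A p-value as small arose in 8 of the 35 splits of the arrays, the real one included, and in 6 without the filter. The others of the 8 kept 3 arrays of a genotype together and so carried part of the genotype difference. Of 33 measured genes of Sm, U snRNP and LSm proteins, 12 fell, 3 rose and 18 did not pass the test (camera adjusted p = 0.0916). Lsm2 fell 1.58-fold, Lsm4 1.38-fold and Snrnp35 1.46-fold, whereas the neuronal Sm protein gene Snrpn rose 1.92-fold and the helicase Snrnp200 rose 1.46-fold. The call of Snrnp35 was lost when all probes of the gene were averaged (adjusted p = 0.0648).

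Of 15 measured genes of the methylosome, the complex in which Prmt5 acts, and of snRNP assembly, 6 fell, 1 rose and 8 did not pass the test (camera adjusted p = 0.0875, and 0.0414 without control 3). Gemin2 fell 2.05-fold, Gemin6 1.70-fold and Ddx20 1.45-fold. Wdr77, the obligate partner of Prmt5, fell 1.37-fold (adjusted p = 0.0184), a call lost without Prmt5-depleted 3 (adjusted p = 0.0537). Coprs, a histone-binding adaptor of Prmt5, rose 1.38-fold (adjusted p = 0.0186), and this call was lost without control 2, Prmt5-depleted 1 or Prmt5-depleted 3 (adjusted p = 0.0502, 0.056 and 0.0583). Among 7 measured genes of the rest of the PRMT family, Prmt2 rose 2.45-fold and Prmt8, a neuronal member not detected on control arrays, rose at least 1.82-fold. Prmt3 fell 1.58-fold, Prmt7 fell 1.43-fold and Carm1 fell 1.47-fold, and Prmt1 and Prmt6 did not pass the test. The median of this family was below 0 at -0.10, its mean was above 0 at 0.15 and camera pointed up without a call (adjusted p = 0.861). It pointed down when any 1 Prmt5-depleted array was left out (adjusted p = 0.625, 0.831, 0.674 and 0.693 without arrays 1 to 4). Prmt8, detected on the 4 Prmt5-depleted arrays alone, then no longer reached 4 detected arrays and left the list. This turn is therefore not a sign that single arrays disagree. For all 4 lists of these machineries the counts adjusted over the list alone were the same.

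Markers of cells outside the neural lineage moved in the same comparison. Of the mesenchymal, pericyte and meningeal markers, 7 passed the detection filter and all 7 rose. Without that filter 16 were measured, 9 rose and 0 fell, and the median log2 change was 0.445 in place of 0.96. The small proteoglycan genes Dcn and Bgn rose 6.09-fold and 5.36-fold, Lum rose at least 3.55-fold and the transcription factor Prrx1 rose 1.81-fold. Camera called the list (adjusted p = 0.00054), but not with an estimated correlation (adjusted p = 0.0501). A p-value as small arose in 2 of the 35 splits, the real one and one that kept 3 arrays of a genotype together. Erythroid markers past the filter were the globin Hba-a1, which rose at least 5.78-fold, and the embryonic globin Hbb-y, which rose at least 1.64-fold (camera adjusted p = 0.0214, and adjusted p = 0.191 with an estimated correlation). No control array detected either gene, so they passed the filter through the Prmt5-depleted arrays alone. Without it 6 erythroid markers were measured, 2 rose and 0 fell, and the median log2 change was 0.283 in place of 2.06. Of 4 endothelial markers past the filter, 3 fell, among them the glucose transporter Slc2a1 at 2.78-fold, Egfl7 at 1.75-fold and Ramp2 at 1.61-fold, and Esam, detected on 2 of 4 control arrays, rose 2.12-fold, or 1.75-fold from the floor (camera adjusted p = 0.11). Without the filter 13 were measured, 4 fell and 2 rose, and the median was 0.043 in place of -0.75. For these 3 lists the counts adjusted over the list alone were the same. Of 3 measured microglia and macrophage markers, Laptm5 rose 3.01-fold and Ctss, detected on 2 of 4 Prmt5-depleted arrays, fell 1.24-fold, or 1.18-fold to the floor (adjusted p = 0.0481), and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.567). The call of Ctss was lost without control 2, 3 or 4 (adjusted p = 0.0549, 0.126 and 0.096) and without Prmt5-depleted 1, 2 or 3 (adjusted p = 0.122, 0.0596 and 0.119). These rises accompanied those of the p53 target genes and neuronal markers on the same 4 arrays.

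Stress and interferon genes were not called as groups. Of 26 measured genes of the integrated stress and unfolded protein responses, 7 fell, 1 rose and 18 did not pass the test, and adjusted over the list alone 6 fell and 1 rose. The serine synthesis enzyme Phgdh fell 2.01-fold, Shmt2 2.28-fold and Pdia4 1.57-fold, and the chaperone Dnajb9 rose 2.13-fold. Camera gave adjusted p = 0.0875 for this list, which passed the threshold without control 1 (adjusted p = 0.0325) or control 4 (adjusted p = 0.00464). Of 10 measured interferon response genes, Ifi27 rose 4.38-fold, Irf9 rose 1.79-fold, Gbp3 fell 1.76-fold and Ifit2 fell 1.54-fold, and 6 did not pass the test, with the same counts adjusted over the list alone (camera adjusted p = 0.861). The list pointed up, but down without control 4 (adjusted p = 0.994) or Prmt5-depleted 2 (adjusted p = 0.894). The call of Ifit2 was lost without control 1, 2 or 4 (adjusted p = 0.0517, 0.0509 and 0.0605) and without Prmt5-depleted 1 or 4 (adjusted p = 0.0642 and 0.0687).

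Fold changes are on a log2 scale with an offset and understate the change of dim genes. Of the 19 lists, only those of p53 target genes, neuronal markers and oligodendrocyte lineage markers were called with an estimated correlation. That setting changes more than the correlation, since it raised the p-value of oligodendrocyte markers although their estimate lay below the preset. Tested against a change of 1.2-fold instead of 0, 1429 genes were higher and 1220 lower.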

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

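The tests of sex, of array brightness and of the genotype calls against the split of the arrays were chosen only after the result was seen, as were the genes Xist, Eif2s3y, Kdm5d and Fos.

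Fos, an immediate early gene, and genes of the sex chromosomes separated single arrays from the others of their genotype. Fos lay at 8.93 on control 4 and at 11.73 to 12.20 on the other controls. Xist, transcribed from the inactive X chromosome of females, lay at 8.97 on control 4 (other controls 4.54 to 4.87) and at 8.88 on Prmt5-depleted 1 (others 4.71 to 4.79). The Y-linked genes Eif2s3y and Kdm5d were low on control 4, at 4.48 (others 8.72 to 9.39) and 4.74 (others 6.97 to 7.09). They were as low on Prmt5-depleted 1, at 4.49 and 4.68, where the other Prmt5-depleted arrays had 8.50 to 9.40 and 6.58 to 7.42. Along the main axis of variation within the genotypes, which held 40.4% of it, control 4 scored 27.74 and the other controls -9.58 to -9.00.

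On this axis control 4 and Prmt5-depleted 1 and 3 lay apart from the others of their genotype. Sex of the embryos was excluded as the whole cause, since Prmt5-depleted 3 had no Xist signal and yet lay 3.2 units from Prmt5-depleted 1 and 29.7 from the nearer of 2 and 4, a difference of 26.6. Mean signal did not follow the split, as only 1 of Prmt5-depleted 2 and 4 was brighter than both 1 and 3. The number of detected probes did follow it. It was 12925 and 13004 on Prmt5-depleted 1 and 3 against 13602 and 13506 on 2 and 4, and control 4 had the fewest of the controls, 12518. A difference in array signal was therefore not excluded. A difference in the immediate early response at harvest may contribute, but the test could not decide this. In it, 11 immediate early genes not looked at before had a median coefficient of -0.26 for these 3 arrays. This lay at percentile 0.53 of 10000 random lists (95% of them between -0.20 and 0.19). Fos and other immediate early genes weighed among the most on the axis, so genes that vary with them would follow it. The random lists drew genes independently, while immediate early genes had an estimated correlation of 0.317, so the percentile is too extreme. With the split as a covariate 99.1% of the genes called between genotypes were still called in the same direction. The axis was drawn from deviations within the genotypes, so the split could move these calls little. The result therefore does not decide whether the split contributes to them.

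Among genes named in the report, 17 groups of 4 arrays held a value far from the other 3. Control 1 was low for Prmt5 at 10.02 (others 10.48 to 10.54) and for Neurog2 at 6.83 (others 8.30 to 8.44). It was high for Sox2 at 10.91 (others 10.44 to 10.50), Laptm5 at 6.16 (others 5.25 to 5.37) and Rad18 at 7.48 (others 7.21 to 7.25). Control 2 was high for Scg2 at 5.67 (others 4.83 to 4.93) and Ugt8a at 8.02 (others 7.44 to 7.50), and control 3 for Gbp3 at 7.30 (others 6.82 to 6.90). Control 4 was high for Coprs at 9.5 (others 9.12 to 9.16), Tbr1 at 6.20 (others 5.95 to 5.99) and Casp1 at 4.72 (others 4.52 to 4.55), and low for Irf9 at 6.12 (others 6.75 to 6.86) and Trp53bp1 at 10.05 (others 10.37 to 10.39). Prmt5-depleted 2 was low for Cpne4 at 8.67 (others 9.74 to 9.96) and Neurog2 at 6.11 (others 6.71 to 6.83). Prmt5-depleted 4 was high for Vgf at 10.07 (others 9.04 to 9.15) and low for Ddx20 at 8.70 (others 8.92 to 8.94).

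Mean log2 values of 3 lists also held a distant array: control 1 for astrocyte markers at 8.16 (others 8.52 to 8.58), control 3 for mesenchymal, pericyte and meningeal markers at 6.18 (others 5.98 to 6.00), and control 4 for the apoptosis machinery at 7.88 (others 7.67 to 7.70). In all, 26 of 250 groups of 4 arrays, 10.4%, held a distant value, where chance gives about 1 in 20 independent groups. The groups share the same arrays and include Xist, Eif2s3y, Kdm5d and Fos, chosen after their values were seen. The excess over chance is therefore not measured by this share.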

How the results depend on the processing

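The 4 alternatives built on the split of the arrays (as a covariate, either side of it alone, and with an estimated correlation) and the one without the 2 arrays with Xist signal were chosen only after the result was seen.

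Prmt5 fell by 2.58 to 2.88 on the log2 scale when any 1 array was left out. The genes higher then numbered 1758 to 2161 and those lower 1873 to 2126. Over the alternatives other than the mean over probes and the 1.2-fold test, 2575 (58.9%) to 4331 (99.1%) of the 4371 genes called were still called, all in the same direction except 1 gene with the 3 arrays. The median change of all genes moved between -0.06 and 0.01. Of 98 named genes, 89 kept their call and direction in every alternative in which they were tested, and 0 of 2045 values reversed. Most were named for a large change or a small adjusted p in these data, so this says little about the other calls. No background correction and the authors' matrix gave the same values but were counted as separate alternatives. The 41 that lost the call belong to Ctss, Ifit2, Ddit4, Coprs, Wdr77, Casp2, Pdia4, Shmt2 and Snrnp35. A block for the replicate number gave 1960 genes higher and 1963 lower. The authors' values gave 2201 and 2211.

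Counts were smaller under stricter settings. Testing against a 1.2-fold change left 1429 genes higher and 1220 lower, and fewer genes passed because of the higher bar. The 3 arrays alone, with 1 control assumed to vary like the others, gave 1434 genes and 1879 probes higher from fewer samples. The strict filter tested fewer genes, 1006 of them higher by at least 1.5-fold. Mdm4, near background, had log2 differences of 0.0081 with the 3 arrays and 0.0273 with the 5, and -0.19 to -0.02 when 1 array was left out.

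With camera at an estimated correlation, the calls of DNA damage (0.0755), replication, mitosis and erythroid markers (0.191 each), mesenchymal markers (0.0501) and SR proteins and hnRNPs (0.199) were lost. The estimate was 0.042 for DNA damage and 0.016 for mesenchymal markers, close to the preset 0.01. For oligodendrocyte markers it was -0.015, and yet the camera p before adjustment rose from 6.74e-05 to 0.00593. This setting therefore changes more than the correlation, and a lost call does not show that the genes vary together. With the array split added to this setting, the adjusted p was 0.0849 for p53 target genes, neuronal and oligodendrocyte markers. It was 0.158 for DNA damage and mitosis, 0.253 for replication and erythroid markers, 0.119 for mesenchymal markers and 0.326 for SR proteins and hnRNPs. At the preset correlation all of these lists stayed called with the split as a covariate.

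Fry, which asks another question, called apoptosis (0.000455), astrocyte (0.0232), endothelial (0.000269), methylosome (0.0167), neural stem (6.91e-05) and PRMT lists (0.0402). The strict filter gave 0.0142 for astrocyte and 0.0172 for endothelial markers. The stress list passed with median scaling (0.0482), no filter (0.0298), array weights (0.00392), the 5 arrays (0.0491) and without the Xist arrays (0.0157). Other gains were the methylosome without a filter (0.0248), neural stem markers with median scaling (0.0297), and Sm proteins with the 5 arrays (0.0373), the covariate (0.0321) or no filter (0.0355). With the 3 arrays endothelial markers passed (0.0295) and oligodendrocyte markers did not (0.0546).

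The uncalled PRMT list pointed down instead of up with the strict filter (0.716), no filter (0.941), the covariate (0.953; 0.961 with an estimated correlation), the 3 arrays (0.705), the 5 (0.521) and without the Xist arrays (0.694). Also uncalled, the stress (0.705) and interferon (0.987) lists reversed with the 3 arrays. Leaving out 1 array gave 0.00464 to 0.205 for stress, 0.625 to 0.994 for interferon, 0.0414 to 0.159 for the methylosome and 0.625 to 0.984 for PRMT genes. Except where stated, the cause was not tested. A block for the slide was not run, as the sources used here name none. Signal over background limits dim genes, since 49% to 53% of probes were detected.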

Other observations

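The 8 further lists, the tests of the neuronal against the oligodendrocyte list, of probe counts, of complete separation and of splits without the detection filter, and the genes named in this part and not in the report were chosen only after the result was seen.

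Among 9 measured genes of dense-core secretory granules 9 rose, the same adjusted over the list alone. Beside Vgf, Scg2 and Chgb, Cadps, a priming factor of granule release, rose 4.72-fold. Of 17 measured genes of the Notch pathway 10 fell, 4 rose and 3 did not pass the test, with the same counts adjusted over the list alone. Beside Mfng, Hes5 and Hes1, the feedback inhibitor Nrarp fell 5.45-fold and the ligand Dll1 fell 3.54-fold, while the ligand Jag1 rose 2.51-fold. Hes5 and Hes1 are also among the neural stem markers.

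Of 19 measured histone genes, 13 fell and 2 rose, with the same counts adjusted over the list alone. H2ac21 fell by 2.89 and H2ac11 fell by 2.77 on the log2 scale, whereas H2ac18 changed by 2.03 and H4c8 by 0.97. Cholesterol biosynthesis fell in 16 of 18 genes measured, among them Tm7sf2 (log2 change -2.21), Nsdhl (-1.43) and Dhcr7 (-1.39), and none rose. Hypoxia response genes fell in 14 of 18, among them the glycolytic enzymes Hk2 (-2.34) and Pfkl (-2.10), the kinase Pdk1 (-2.10) and the growth factor Vegfa (-2.12), and none rose. This list shares Slc2a1 with the endothelial markers. For both lists the counts adjusted over the list alone were the same. These 5 lists were drawn up from the same data, and some hold the genes that prompted them, so their camera p-values, printed below only beside those of other splits, are circular and are not read as tests. None of the 8 further lists was called with an estimated correlation, where the lowest adjusted p was 0.148.

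The other 3 lists were not called with camera. Of 5 choroid plexus markers 3 rose, and 4 adjusted over the list alone (adjusted p = 0.0818). Ttr, the main transcript of that tissue, ranged from 4.61 to 14.41 over the 8 arrays. Of 17 immediate early genes 3 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.928). Of 32 cytosolic ribosomal protein genes 5 fell, and 2 adjusted over the list alone (adjusted p = 0.386).

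The 8 arrays can be split into 4 and 4 in 35 ways, the real one included. Only 1 of the 35 splits, the real one, called as many as 4371 genes and 6169 probes. The other 34 called 0 with limma, although up to 1078 genes had an unadjusted p under 0.05. They mix the genotypes, whose difference then widens the spread within each side, so few calls could arise there. The real split also separated the most genes completely (4031, highest other 463). First of 35 is the best rank possible, and it makes chance unlikely without excluding it. For lists the measure was the camera p before adjustment. Only the real split, 1 of 35, gave a value as small for p53 target genes (1.15e-08, smallest other 2e-08), neuronal markers (1.75e-11, 7.24e-08), oligodendrocyte markers (6.74e-05, 0.000705) and DNA damage (6.4e-05, 0.000118). The same held without the detection filter. This rank too is the best possible, was not adjusted over the lists, and does not exclude chance. Counting the real split, a value as small arose in 8 splits for SR proteins and hnRNPs (0.00175, smallest other 2.93e-05), 2 for mitosis (3.35e-11, 7.5e-12), 6 for replication (2e-12, 2.2e-15) and 2 for mesenchymal markers (0.000199, 0.000109). Without the filter these counts were 6, 1, 1 and 2. Each other split with a value as small in the filtered data kept 3 arrays of a genotype together, so it carried part of the genotype difference. For erythroid markers 1 split of 35, the real one, had a value as small (0.0102; 0.0199), but the filter favoured it, and without the filter 8 splits did (0.017; 0.000175), so chance was not excluded. For lists drawn up from these data the counts exclude nothing: 1 for the Notch pathway (0.00654; 0.0123), 1 for secretory granules (1.14e-07; 9.9e-06), 1 for histones (6.25e-05; 0.000409), 5 for hypoxia (6.19e-06; 1.66e-08) and 4 for cholesterol (1.86e-06; 2.49e-08).

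Neuronal markers rose while oligodendrocyte lineage markers fell, with list medians of 1.59 and -1.27 (1.55 and -1.27 with undetected genes at their bound). The opposite signs held over 4 scalings, with a neuronal median of at least 1.29 and an oligodendrocyte median of at most -0.975, a distance from 0 of 0.975 or more. All 4 scalings left the median gene near 0 (log2 change -0.04 to 0.01). The signs are therefore relative to the typical gene, and a shift shared by most genes was not tested. A lower share of progenitors, fewer cells of the oligodendrocyte lineage and lower expression per cell cannot be told apart, since progenitors also express part of the oligodendrocyte genes. The gap of 2.85 between the medians, seen before it was tested, and the falls over a range of 4.86 log2 units, from Olig1 (-0.48) to Pdgfra (-5.34), therefore exclude none of them. An effect of Prmt5 loss on the choice of lineage stays open as a hypothesis and was not tested.

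Probes of 20 genes were called in opposite directions, among 948 genes with at least 2 called probes. Among those with both sides detected on all 8 arrays, the widest differences, named after the values were seen, were in Ptpre and Klc1. In Ptpre, a receptor tyrosine phosphatase, ILMN_2826916 rose 6.23-fold and ILMN_1254630 fell 1.74-fold, and in Klc1, a kinesin light chain, ILMN_2671411 rose 4.11-fold and ILMN_3042059 fell 1.48-fold. The other splits called 0 probes, so that only 1 of 35 splits, the real one, had as many such genes (highest other 0) says nothing about chance. At least 15 of the 20 genes kept the opposite calls under each of no background correction, cyclic loess and median scaling. These settings centre the genes nearly alike, so a shift shared by most genes was not tested. Dim probes were excluded as the whole cause, as 15 had a called probe on both sides detected on all 8 arrays. Both sides changed by at least 1.5-fold in 7 genes. A shift between transcript isoforms may underlie some of them, but where the probes lie and whether they bind other transcripts was not analysed here.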
